A study of Mus musculus with 14 samples.

How the data were processed

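RNA sequencing values from 14 mouse libraries in 6 groups were used. Whole adult testis gave 3 control libraries (genotype Tsga8+/Y) and 3 knockout libraries (Tsga8-/Y). The other 8 libraries came from tissue enriched for spermatids by laser capture microdissection, in which chosen cells are cut from a tissue section under a microscope. One captured region held round spermatids of steps 4 to 8, and the other held round spermatids of steps 1 to 3 with elongated spermatids of steps 9 to 16. Each region had 2 control and 2 knockout libraries. Per the labels' protocols, whole testis RNA went through a directional library kit (NEBNext Ultra Directional), and captured RNA through SMART-seq2, a protocol for very small RNA amounts that copies polyadenylated RNA without marking its strand. No gene was therefore tested for a difference between whole testis and captured tissue. Ratios of control levels between the 2 served only to rank and to match genes, and these ratios also hold the difference between kits. The series text speaks of 2 or 3 replicate animals. The labels do not say whether the captured regions of one genotype came from the same animals. Libraries were treated as separate samples, with a block for a shared animal as an alternative.

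The authors deposited 1 table with a log2 RPKM value (reads per kilobase of gene length, scaled to library depth) for each of 25965 gene symbols in each library. Per the submitters' processing notes, FastQC, Trim Galore 0.4.0 and HISAT2 2.1.0 were used with the mm10 genome. The counting tool, its annotation and its use of strand are not given in the sources used here. The plan, fixed before the data were examined together with the lists, tests and alternatives below, had assumed RPKM, so the deposited log2 values were first raised back to RPKM. The length behind each RPKM was the whole gene span on the genome, introns included, so a compact gene and a long gene with equal transcript numbers have unequal RPKM. The median span was 13.356 kb. Genes with 0 reads had been entered as if they had 0.9 read. No symbol stood in the table more than once.

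With these lengths, whole read counts could be recovered: 99.99% of all values lay within 0.05 of a whole read, and 100% of those below 1000 reads, which were 74.8% of the values. The number of reads behind the RPKM scale was 30388500 to 49147300 per library in whole testis and 23467200 to 72022300 in captured tissue. An RPKM of 1 in whole testis stood for 454.1 reads at the median gene span and the median depth, and for fewer reads in compact genes. Recovery returned the true reads for 100% of 2000 simulated genes. No replicate pair was close enough to be 1 library deposited more than once: chi-square per gene between the recovered reads of replicates was 10.9 to 557.6.

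Genotypes and regions were compared with limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), moderated with an intensity trend. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and all tests were two-sided unless named otherwise. A fold change on this scale understates the change of genes with low levels. The 6 whole testis libraries had their own fit, over genes with an RPKM of at least 1 in at least 3 libraries. The 8 captured libraries shared 1 fit with 4 group means, over genes with an RPKM of at least 1 in at least 2 libraries. That fit gave the genotype difference in each region, the difference between those differences, and the region difference in each genotype. Values are means ± SD of RPKM, or log2 differences ± SE.

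Gene lists were tested with camera, which compares a list with all other tested genes, at a preset correlation between genes of 0.01, with adjustment over the lists of a comparison. Camera with an estimated correlation and fry, which asks whether a list moves one way on balance, were run beside it. The 28 lists covered spermatogonia, meiotic prophase, pachytene and secondary spermatocytes, the acrosome, chromatin condensation, head shaping with perinuclear theca and manchette, tail fibres and sheaths, the axoneme, ion channels and transporters, testis kinases and spermatid energy metabolism, spermatid transcription and RNA regulators, sex-linked spermatid families, the piRNA pathway, p53 and apoptosis, the unfolded protein response, heat shock, immediate early genes, the interferon response, Sertoli, Leydig, peritubular, macrophage, endothelial and red blood cells, ribosomal proteins, oxidative phosphorylation, the proteasome and mitochondrially encoded genes. Genes on the X and the Y chromosome were added as lists from the table's own positions. A list needed 5 tested members. Enrichment of calls on a chromosome, and overlap of calls, was tested with a one-sided Fisher's exact test.

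Named genes followed a rule: Tsga8, then per direction the 10 genes with the largest change among called genes whose groups did not overlap, leaving out symbols of predicted genes (81 higher and 63 lower in whole testis). With fewer calls, up to 5 per direction with the smallest p were named as values that did not pass. Up to 4 members of each list described were added by smallest p. Region differences and the difference between regions had 5 per direction. Genes of multi-copy families (Cypt, Ube2dnl, olfactory receptor and Y-linked genes) can share reads with near-identical copies, and genes overlapped by an antisense gene can hold its reads, so their levels are uncertain.

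Alternatives were pseudocounts of 0.1 and 4, no filter, a mean RPKM of at least 5, scaling to a common sum, median centring, quantile normalization, no intensity trend, quality weights per library, the replicate number as a block, each library left out in turn, a minimum log2 change of 1 and, for captured tissue, a fit of the compared libraries alone and a block for a shared animal between regions. Added after the data were seen were limma voom on the recovered reads (genes with at least 10 reads), the X chromosome list without Tsga8 and the sex-linked families, and whole testis without both libraries numbered 1. In whole testis the replicate numbers paired the libraries in part: deviations of same-numbered control and knockout libraries from their group means correlated at 0.329, 0.362 and 0.148. Differently numbered libraries correlated at -0.442 to 0.299, the highest being control 3 with knockout 2. This pairing comes from the data, as the labels do not say what a number stands for. In captured tissue the same check gave 0.061 and 0.0992. Same-numbered libraries of the captured regions correlated at -0.00912 in controls and 0.18 in knockouts. Numbers there were taken as names.

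The procedure was tested on simulated data with known changes. In whole testis (7985 genes in the fit) limma recovered 77.6% of genes changed by 0.5 on the log2 scale and 95.7% of those changed by 1. In the fit for steps 4 to 8 (7355 genes) it recovered 0% at 1, 31.2% at 2 and 60.9% at 3, and for steps 1 to 3 and 9 to 16 (7332 genes) 2.13% at 1, 29.5% at 2 and 55.6% at 3. Camera called 0 of 100 random lists in each comparison. The simulated genes varied independently, so this could not show false calls that come from correlation between genes. In the data that correlation was estimated at 0.793 for the Sertoli cell list in whole testis. Exons of Tsga8 and the GC content of transcripts were taken from the GENCODE annotation of GRCm38, the assembly that mm10 names.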

Results

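Adult testes of mice without Tsga8, an X-linked gene active in spermatids, were compared with those of control males, in a study of what the gene does for spermatid shaping and male fertility. Whole testis was measured in 3 control and 3 knockout libraries. Captured spermatids were measured in 2 libraries per genotype from each of 2 regions of the seminiferous epithelium. Steps 4 to 8 are round spermatids in which the acrosome spreads over the nucleus. The second region held early round spermatids of steps 1 to 3 beside elongating and condensed spermatids of steps 9 to 16. The RPKM scale rested on 30388500 to 49147300 reads per library in whole testis and 23467200 to 72022300 reads in captured tissue. Replicates were ranked alike with Spearman correlations of 0.966 to 0.989 across genes in whole testis and 0.726 to 0.836 in captured tissue. The median SD of a gene between replicates was 0.0911 to 0.105 on the log2 scale in whole testis and 0.299 to 0.439 in captured tissue.

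Tsga8 itself was strongly reduced in every knockout library. In whole testis it stood at 99.8 ± 9.72 RPKM in controls and 2.64 ± 0.540 RPKM in knockouts (SD, n = 3 each), 2.65% of the control level. The limma log2 difference was -4.79 ± 0.13 (adjusted p = 3.05e-06). In tissue of steps 4 to 8 it was 216 ± 32.4 RPKM in controls and 2.97 ± 1.11 RPKM in knockouts (n = 2 each). In tissue of steps 1 to 3 and 9 to 16 it was 133 ± 108 RPKM in controls, from libraries at 56.9 and 209 RPKM, and 8.19 ± 1.75 RPKM in knockouts. The captured differences of -5.79 ± 0.65 and -3.60 ± 0.65 did not pass the threshold (limma adjusted p = 0.0569 and 0.194). The genotypes did not overlap in either region, which also held for 29.0% and 35.7% of all tested genes there. The gene lies on chromosome X from 83486678 to 83487924 (mm10) on the minus strand and has 2 exons, from 83487571 to 83487924 and from 83486678 to 83487393, both partly coding. Reads remained in all knockout libraries, with 109, 118 and 138 reads in whole testis. The labels do not state which part of the gene was deleted, so these reads cannot be assigned to a remaining piece.

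**Figure D1:**
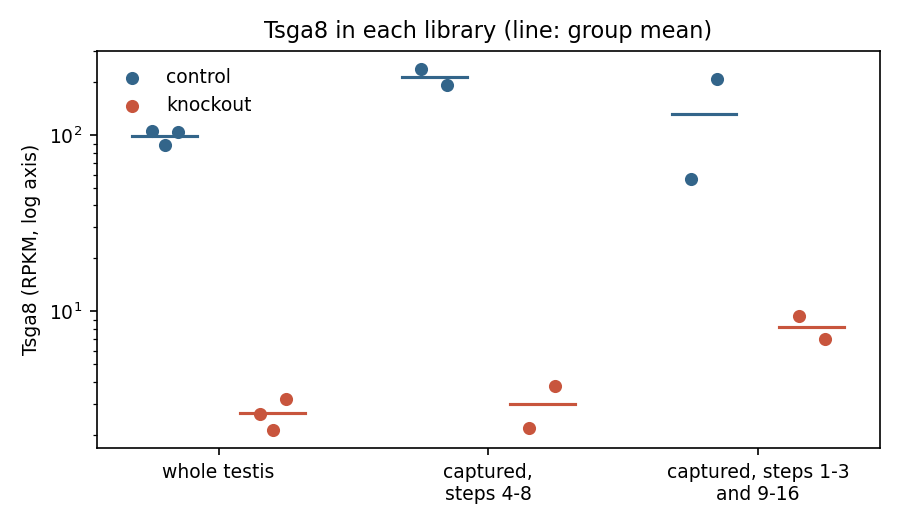
Tsga8 level (RPKM, log axis) in each of the 14 libraries, with 1 point per library and a line at the group mean, for whole testis and both captured regions. Whole testis controls lie at 88.6 to 106 RPKM and knockouts at 2.12 to 3.20 RPKM, and every knockout point lies below every control point of its tissue.

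Beyond Tsga8, the largest losses in knockout whole testis were of genes on the X chromosome. Dusp21, a dual-specificity phosphatase, fell from 12 ± 2.06 to 0.536 ± 0.179 RPKM (SD, n = 3 each), a log2 difference of -3.07 ± 0.14 (adjusted p = 5.16e-05). The zinc finger gene Zcchc13 fell from 26.3 ± 4.16 to 4.74 ± 0.956 RPKM, and the tetraspanin Tspan6 from 14.2 ± 1.87 to 2.96 ± 0.411 RPKM. Prdx4, a peroxidase of the endoplasmic reticulum, fell from 8.52 ± 0.880 to 2.1 ± 0.0347 RPKM. Cypt3 and Cypt1, members of a family of basic proteins of the perinuclear theca, fell from 72.9 ± 8.48 to 16.6 ± 2.98 RPKM and from 99.3 ± 17.2 to 32.4 ± 4.30 RPKM, and Ube2dnl, related to ubiquitin-conjugating enzymes, from 7.95 ± 0.996 to 1.17 ± 0.493 RPKM. The autosomal genes with the largest named losses were Kpna1, an importin of the nuclear pore pathway, at 14.8 ± 3.97 against 4.49 ± 2.66 RPKM (adjusted p = 0.0307), and the zinc finger gene Zfp791 (log2 difference -1.47 ± 0.22, adjusted p = 0.0141). Kpna1 lost its call without any one of controls 2 and 3 and knockouts 2 and 3 (adjusted p = 0.0793, 0.0952, 0.113 and 0.135), and Zfp791 without control 3 or knockout 3 (0.0604 and 0.0694). Without a filter neither was called (0.0926 and 0.0652). The other 8 of these 10 genes were called under every alternative in which they were tested.

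X-linked genes as a class were lower in knockout whole testis. Of 185 tested X-linked genes 81 fell (43.8%) and 3 rose, against 85 of 7961 genes elsewhere that fell (1.07%; one-sided Fisher's exact test across genes, which are not independent, p = 1.8e-94). The 81 genes made up 48.8% of all lower calls and lay along the whole chromosome. Adjusted over the list alone, 93 X-linked genes were lower and 13 higher. Their median log2 difference was -0.30, against 0.090 for all tested genes, and camera called the list (adjusted p = 1.26e-36). The adjusted p was 0.0812 with an estimated correlation and 0.0054 by fry. The median was -0.11 without control 1, -0.16 without control 2, -0.13 without both libraries numbered 1, -0.59 with a common sum, -0.93 at a mean RPKM of at least 5 and -0.017 without a filter. With pseudocounts of 0.1 and 4 it was -0.48 and -0.12. Without Tsga8 and the sex-linked families the median was -0.24 over 175 genes (adjusted p = 6.86e-32). The list of sex-linked spermatid families had 7 of 12 tested members lower, 9 adjusted over the list alone, with a median of -0.83 (adjusted p = 4.43e-11; adjusted p = 0.621 with an estimated correlation), which was -0.035 without a filter. Among them, besides Cypt3 and Cypt1, were Actrt1 (-1.47 ± 0.15, adjusted p = 0.00298), an actin-related protein of the sperm head, and Tex13a (-0.95 ± 0.10, adjusted p = 0.00371). Lower X-linked genes numbered 38 of 149 tested without control 2, 38 of 151 without control 3 and 53 of 182 without knockout 3. They numbered 29 of 45 at a mean RPKM of at least 5 and 237 of 739 by limma voom on recovered reads. With a control left out the filter still asked for 3 libraries, so genes low in knockouts could drop out (148 tested without control 1). The medians without a control thus cover fewer genes.

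**Figure D2:**
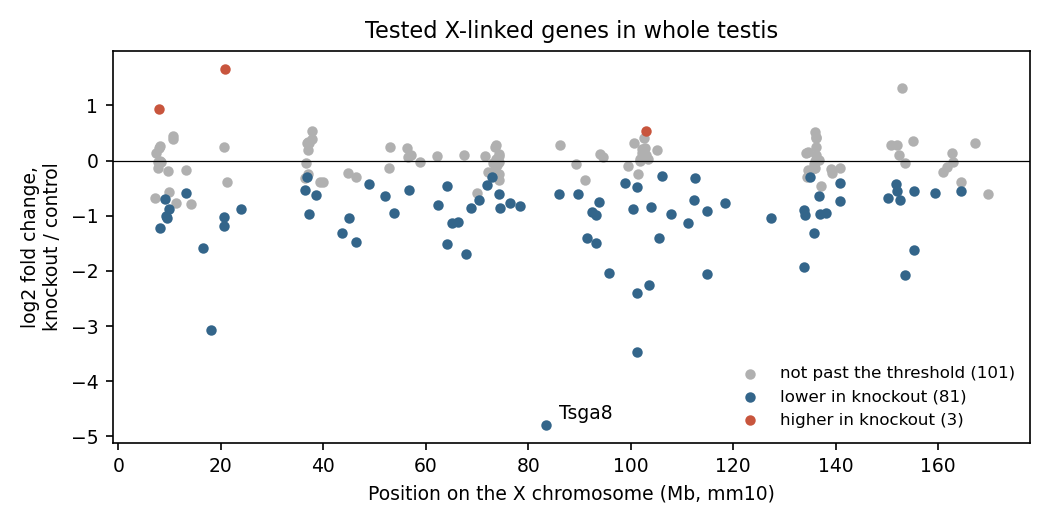
Each point is 1 of 185 tested X-linked genes in whole testis, by position on the X chromosome (Mb, mm10) and log2 difference of knockout against control, coloured by call. The 81 lower genes are spread along the chromosome, Tsga8 is the lowest point at -4.79, and 3 genes are higher.

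Nearly all genes called higher in knockout whole testis lay outside the X chromosome, as did nearly all tested genes (7961 of 8146). Tnfrsf12a, a receptor of the tumour necrosis factor family, rose from 0.345 ± 0.270 to 3.61 ± 1.44 RPKM (log2 difference 1.74 ± 0.23, adjusted p = 0.00906, n = 3 each). Timp1, an inhibitor of matrix metalloproteinases on the X chromosome, rose from 0.115 ± 0.111 to 2.74 ± 1.39 RPKM (adjusted p = 0.018), Rundc3a from 2.71 ± 0.228 to 7.03 ± 1.5 RPKM (adjusted p = 0.00746) and Aplp1, a relative of the amyloid precursor protein, from 1.02 ± 0.215 to 4.37 ± 1.53 RPKM (adjusted p = 0.012). Smaller increases were called for Ly6e (1.07), Ptms (1.04), CAAA01154301.1 (1.03), Pcsk1n (0.94) and the small heat shock protein Hspb1 (0.94 ± 0.22, adjusted p = 0.0465), which lost its call in the fit with the replicate number as a block (adjusted p = 0.0595). Of the 10 named higher genes, only Tnfrsf12a and Rundc3a kept their calls in each fit without 1 library in which they were tested. Tnfrsf12a, below an RPKM of 1 in controls, was not tested without a knockout, as the filter still asked for 3 libraries. Without a filter, with more genes to adjust for, none of the 10 was called. Immediate early genes, which respond within minutes to many stimuli including tissue handling, had 5 of 9 tested members higher and 0 lower, 6 adjusted over the list alone. They included Junb (1.05 ± 0.526 against 3.32 ± 0.518 RPKM, adjusted p = 0.0176), Ier2 (0.76 ± 0.10), Jun (0.75 ± 0.14) and Btg2 (0.65 ± 0.10). That list had a median of 0.43 (camera adjusted p = 0.0116; adjusted p = 0.621 with an estimated correlation), and its call ended when both libraries numbered 1 were left out (adjusted p = 0.316), with a median of 0.28 without knockout 3. Sertoli cell markers, from the somatic cells that nurse the germ cells, had 2 of 18 higher, Vim (0.76 ± 0.18, adjusted p = 0.0487) and Ctsl (0.73 ± 0.17, adjusted p = 0.0497), 5 adjusted over the list alone. Their median was 0.41 (adjusted p = 0.00682; adjusted p = 0.872 with an estimated correlation), and the call ended at a mean RPKM of at least 5 (adjusted p = 0.149). The mean log2 level of the Sertoli list was 3.38, 2.88 and 2.84 in controls 1 to 3 and 3.39, 3.35 and 3.60 in knockouts 1 to 3, so control 1 lay among the knockouts.

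In all, 501 of 8146 tested genes were called in whole testis, 335 higher and 166 lower, and 2370 had an unadjusted p under 0.05. Control and knockout libraries stood wholly apart for all 501 and for 32.8% of all tested genes, where chance gives 10%. The balance of directions depended on the scale: 91 genes were higher and 131 lower with libraries scaled to a common sum, 194 and 310 with median centring, and 157 and 216 with quantile normalization. Of the 335 higher genes 90, 193 and 153 kept their calls. The number called also depended on single libraries. It was 1466 without control 1 and 1129 without knockout 1, but 76 without control 2, 68 without control 3, 83 without knockout 2 and 74 without knockout 3, and 2674 without both libraries numbered 1. With the replicate number as a block it was 511 higher and 229 lower, among them 285 of the 335 higher and 161 of the 166 lower genes. Limma voom on recovered reads called 796 higher and 1603 lower of 19140 genes, among them 164 of the 166 lower and 296 of the 335 higher genes.

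Most lists of spermatid structures did not pass in whole testis. The acrosome list had 0 of 21 tested members called (median 0.080, adjusted p = 0.635) and the chromatin condensation list 0 of 16 (median -0.038, adjusted p = 0.0764). The latter includes Prm1, a protamine of sperm chromatin, at 2771 ± 892 RPKM in controls and 1541 ± 310 RPKM in knockouts (log2 difference -0.81 ± 0.28, adjusted p = 0.11). Head shaping genes had 2 higher (Klc3 and Spag4) and 2 lower (Actrt1 and Cylc1) of 22, with a median of 0.15 but a camera direction towards lower (adjusted p = 0.943). Tail fibre and sheath genes had 1 of 25 lower (Fsip2; adjusted p = 0.761), ion channels 0 of 10 (adjusted p = 0.683) and kinases with energy metabolism 0 of 20 (adjusted p = 0.683). Axoneme genes had 1 of 8 higher (Rsph6a), and 4 higher and 1 lower adjusted over the list alone. They did not pass by camera (adjusted p = 0.405) but passed towards higher by fry (adjusted p = 0.0103), with mean log2 levels of 2.73 to 2.76 in controls and 2.90 to 2.95 in knockouts. Spermatid transcription and RNA regulators had Ybx2 higher and Paip2 lower of 19 (adjusted p = 0.284; 3 higher and 2 lower adjusted over the list alone).

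Meiotic and RNA-silencing genes were slightly lower as lists in whole testis. Of 14 meiotic prophase genes, Smc1b (-0.32 ± 0.07, adjusted p = 0.0371), a meiotic cohesin, and Tex15 (-0.42 ± 0.09, adjusted p = 0.0446) fell, 4 were lower and 1 higher adjusted over the list alone, and the median was -0.11 (camera adjusted p = 0.00247; adjusted p = 0.621 with an estimated correlation). It was -0.071 without control 1, -0.18 without control 3 and -0.059 without knockout 3. The piRNA pathway had 0 of 12 called, also adjusted over the list alone, with a median of -0.15 (adjusted p = 0.00411; adjusted p = 0.621 with an estimated correlation), and Ddx4, a germ cell RNA helicase, at -0.25 ± 0.09. Its call ended without a filter (adjusted p = 0.0954), at a mean RPKM of at least 5 (0.0694) and with limma voom (0.0658). The median was -0.095 without control 1, -0.25 without knockout 1 and -0.087 without knockout 2. Oxidative phosphorylation genes had 0 of 68 called and a median of 0.17 (adjusted p = 0.0128; adjusted p = 0.984 with an estimated correlation), and that call ended without control 2 (median 0.11, 0.447), without knockout 3 (0.0992), with quantile normalization (0.16) and at a mean RPKM of at least 5 (0.478). Not past the threshold by camera were pachytene and secondary spermatocyte genes (13 tested, adjusted p = 0.809), p53 and apoptosis (8, 0.926), the unfolded protein response (15, 0.136, with Ddit3 higher and 5 higher adjusted over the list alone, though fry passed towards higher with adjusted p = 0.0379), heat shock (10, 0.978, with Hspb1 higher and Hspa4l lower), Leydig cells (11, 0.683), peritubular cells (5, 0.357), ribosomal proteins (82, 0.0552) and the proteasome (32, 0.683, with X-linked Psmd10 lower). Too few members were tested for spermatogonia (2 of 16 in the table), macrophages (4 of 15, with H2-Ab1 higher), endothelial cells (1 of 12), the Y chromosome (2 of 378, with Eif2s3y lower) and the interferon response, red blood cell and mitochondrially encoded lists (0 each).

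In captured round spermatids of steps 4 to 8, X-linked genes as a list were also lower in knockouts. Of 213 tested X-linked genes 161 had a negative difference (75.6%), with a median of -0.72 (camera adjusted p = 4.96e-21; adjusted p = 0.0187 with an estimated correlation). The sex-linked spermatid families had a median of -1.22 over 14 genes (adjusted p = 2.04e-08; adjusted p = 0.0338 with an estimated correlation), with Cylc1 at -1.52 ± 0.46, Cypt3 at -2.01 ± 0.64, Cypt1 at -1.59 ± 0.58 and Cypt2 at -1.56 ± 0.58 (n = 2 each). These 2 lists kept their calls under every alternative run, but the median of the families was -0.74 without knockout 1. Without a filter the medians were -0.0052 and -0.50. Y-linked genes had a median of -0.64 over 19 genes (adjusted p = 1.13e-05; adjusted p = 0.274 with an estimated correlation), lost without control 1 (0.0679) or knockout 2 (0.183). The median was -1.02 without control 2 and -0.0063 without a filter. Genes of chromatin condensation had a median of -0.54 over 15 genes (adjusted p = 0.00218; adjusted p = 0.41 with an estimated correlation), with Prm1 at -2.79 ± 1.04, lost without control 2 (0.0666) or knockout 1 (median -0.25, 0.0981). Head shaping genes had a median of -0.27 over 22 genes (adjusted p = 0.0474; adjusted p = 0.508 with an estimated correlation). That call was lost under each of the 3 scalings (0.0957, 0.055 and 0.101), without a filter (-0.13, 0.0671), at a mean RPKM of at least 5 (0.0751), with a pseudocount of 0.1 (0.0583), with limma voom (0.164) and without control 2 (median 0.0044, adjusted p = 0.898) or knockout 2 (-0.14, 0.573). The median was -0.41 without control 1. Sertoli cell markers had a median of 0.63 over 15 genes (adjusted p = 0.000825; adjusted p = 0.548 with an estimated correlation), with Inha at 1.46 ± 0.42 and Clu at 1.78 ± 0.91, lost without control 2 (median 0.24, 0.167) or knockout 2 (0.39, 0.437), without a filter (0.0671) and with limma voom (0.109), and the median was 1.06 without control 1.

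No single gene passed in steps 4 to 8: limma called 0 of 7857 genes, with 285 at an unadjusted p under 0.05 where chance gives 392.8. Limma voom called 0 of 19797, with 612 at an unadjusted p under 0.05, also fewer than chance gives for that many genes. Adjusted over the list alone, 10 X-linked genes were lower. The lowest p after Tsga8 among named genes went to the X-linked Wdr13 (-2.19 ± 0.38, adjusted p = 0.332), Dusp21 (-4.66 ± 0.81, adjusted p = 0.332) and Fam122c (-1.84 ± 0.38), and to the olfactory receptor gene Olfr742 (-1.74 ± 0.36). On the higher side were Olfr181 (2.40 ± 0.53), Sertad4 (1.92 ± 0.43), the tetraspanin Cd81 (1.69 ± 0.40), Prr15 (1.88 ± 0.45) and Pop7 (3.04 ± 0.75). The other lists did not pass in this region (adjusted p = 0.121 or higher).

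In the region with steps 1 to 3 and 9 to 16, the sex-linked spermatid families were lower in knockouts, while X-linked genes as a list did not pass. The families had a median of -0.85 over 14 genes (camera adjusted p = 0.000329; adjusted p = 0.22 with an estimated correlation; 2 lower adjusted over the list alone), with Cypt3 at -2.82 ± 0.64 and Cypt12 at -1.76 ± 0.51 (n = 2 each), and kept the call whichever library was left out, with a median of -1.29 without control 2 and -0.23 without a filter. The median of the 213 X-linked genes was -0.080 (adjusted p = 0.178; 13 lower and 4 higher adjusted over the list alone). It was -0.81 at a mean RPKM of at least 5 (adjusted p = 2.59e-10), -0.14 without knockout 1 (adjusted p = 0.0279) and 0.15 with libraries scaled to a common sum, where all genes moved to a median of 0.30 (adjusted p = 0.00463, towards lower). Chromatin condensation genes had a median of -0.80 over 15 genes (adjusted p = 0.00381; adjusted p = 0.729 with an estimated correlation), with the transition protein Tnp1 at -1.68 ± 0.81 and Prm1 at -2.06 ± 1.04, lost without control 1 (0.131) or knockout 2 (0.08). The median was -1.33 without control 2. Acrosome genes had a median of 0.65 over 21 genes (adjusted p = 0.0104; adjusted p = 0.729 with an estimated correlation), with the hyaluronidase Spam1 at 1.76 ± 0.49, and Sertoli cell markers 0.66 over 15 genes (adjusted p = 0.0428; adjusted p = 0.787 with an estimated correlation). Without control 1 these medians were -0.070 (adjusted p = 0.75) and -0.11 (0.836). In a fit of the 4 libraries of this region alone the chromatin condensation, acrosome and Sertoli lists did not pass (adjusted p = 0.058, 0.0541 and 0.0541). The acrosome median was 0.41 without knockout 1 and the Sertoli median 1.28 without control 2. The Sertoli list was also lost without knockout 2 (0.0835), without a filter (median 0.077, 0.376), with limma voom (0.112), with quantile normalization (0.0648) and with a pseudocount of 4 (0.0562). Proteasome genes had a median of 0.44 over 33 genes (adjusted p = 0.00381; adjusted p = 0.787 with an estimated correlation), lost without control 2 (0.292) or knockout 2 (0.0991) and at a mean RPKM of at least 5 (0.103). Control 1 of this region stood apart from control 2, with Prm1 at 35227 against 6425 RPKM and 6.99% of gene reads in its 4 most abundant genes against 2.37%.

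Single genes did not pass in this region either. Limma called 0 of 7857 genes, with 525 at an unadjusted p under 0.05 where chance gives 392.8. Limma voom called 0 of 19797, with 761 at an unadjusted p under 0.05, which is fewer than chance gives for that many genes. Named genes on the lower side were Wdr13 (-2.32 ± 0.38, adjusted p = 0.134), Tspan6 (-2.33 ± 0.48), Dusp21 (-3.89 ± 0.81) and Zfp41 (-1.64 ± 0.36). On the higher side were Vmn1r40 (2.94 ± 0.41, adjusted p = 0.124), Timp1 (2.22 ± 0.35), Rabggtb (2.27 ± 0.36), Trav9n-1 (2.17 ± 0.37) and the spindle checkpoint kinase Bub1 (2.04 ± 0.38). The lists not named here did not pass (adjusted p = 0.172 or higher).

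The genotype difference of sex chromosome genes was itself compared between the regions. The median difference of X-linked genes was 0.55 higher on the log2 scale in the region with steps 1 to 3 and 9 to 16 than in that with steps 4 to 8 (camera adjusted p = 1.63e-07; adjusted p = 0.131 with an estimated correlation), and that of Y-linked genes 0.72 higher (adjusted p = 4.97e-05; adjusted p = 0.472 with an estimated correlation). The X result was not past the threshold without a filter (median 0.020, 0.108) or at a mean RPKM of at least 5 (0.241), and the Y result not without control 1 (0.0552) or knockout 2 (0.0962) of steps 4 to 8, while it was 0.47 without knockout 1 of the other region and 0.033 without a filter. No other list passed (adjusted p = 0.0826 or higher). Limma called 0 of 7857 single genes, with 223 at an unadjusted p under 0.05, and limma voom 0 of 19797 with 480. The named genes by smallest p were Rabggtb (2.71), Vmn1r40 (2.64), AC192547.2 (2.21), Apoo-ps (2.61) and Timp1 (2.13) on the higher side, and Fahd1 (-3.98), C1qbp (-2.21), Emp3 (-2.49), the malate dehydrogenase Mdh1 (-2.1) and Sertad4 (-2.21) on the lower side.

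**Figure D3:**
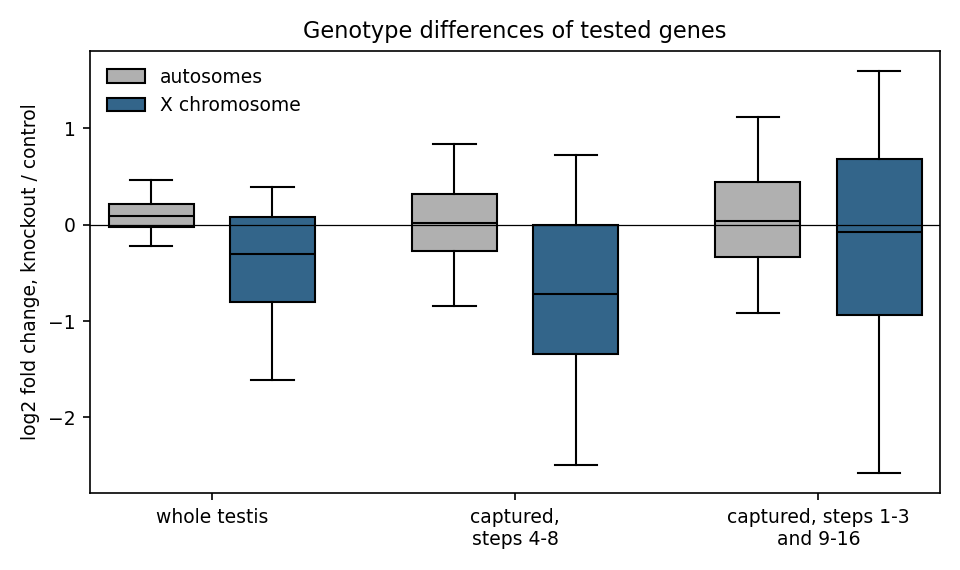
Log2 differences of knockout against control for tested autosomal genes (grey) and X-linked genes (blue) in whole testis and both captured regions. Boxes span the quartiles, lines mark medians and whiskers reach from the 5th to the 95th percentile. X-linked medians are -0.30, -0.72 and -0.080, the last of which is 0.15 with libraries scaled to a common sum, where that of all genes is 0.30.

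Genes lower in whole testis lay mostly on the same side in captured tissue, whose libraries are separate. Of the 136 lower calls that were also tested in captured tissue, 117 (86.0%) had a negative difference in steps 4 to 8, where 48.1% of all genes did, and 101 (74.3%) in steps 1 to 3 and 9 to 16, where 48.3% did. Among 78 X-linked calls these numbers were 76 and 57. The 270 higher calls showed no such tendency, with 140 (51.9%) and 125 (46.3%) on the higher side. No call was shared at the adjusted threshold, since captured tissue had 0 calls in limma and in limma voom. At an unadjusted p under 0.01, 24 lower genes were shared between whole testis and steps 4 to 8 where 1.14 would be for independent lists (one-sided Fisher's exact test p = 5.69e-28), among them Tsga8, Dusp21, Prdx4, Tspan6, Wdr13 and Cylc1. Whole testis shared 16 lower genes with steps 1 to 3 and 9 to 16 (1.58 for independent lists, Fisher's exact test p = 1.17e-12), and the captured regions shared 15 (0.41, Fisher's exact test p = 1.76e-20). The captured regions shared 1 fit and so 1 estimate of spread per gene. Their lists are thus not independent, and 0.41 and its p overstate the contrast. Shared higher genes were 3, 8 and 1 (Fisher's exact test p = 0.23, 0.123 and 0.218).

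Between the captured regions of control mice, genes of the acrosome were lower in the region with steps 1 to 3 and 9 to 16 than in steps 4 to 8. Their median was -1.20 over 21 genes (camera adjusted p = 8e-04; adjusted p = 0.386 with an estimated correlation), with Spam1 at -1.71 ± 0.49, Izumo1, the sperm ligand for the egg surface, at -2.48 ± 0.84 and Zp3r at -1.35 ± 0.47 (n = 2 each), and the call held whichever library was left out. Its size rested on control 1 of steps 1 to 3 and 9 to 16, without which the median was -0.26 (adjusted p = 0.00393). X-linked genes had a median of -0.38 (adjusted p = 0.000206; adjusted p = 0.331 with an estimated correlation), lost without a filter (median 0.0024, adjusted p = 0.105) and with limma voom (0.0070, 0.0869), and the median was -0.22 without control 2 of steps 4 to 8. Y-linked genes had a median of -0.67 (adjusted p = 8e-04; adjusted p = 0.386 with an estimated correlation), lost without control 1 of steps 4 to 8 (median -0.43, 0.0565). The median was -0.0029 without a filter. Ribosomal protein genes were higher, with a median of 0.49 over 81 genes (adjusted p = 8e-04; adjusted p = 0.608 with an estimated correlation), lost without control 2 of steps 4 to 8 (median 0.030, 0.489), and the median was 0.95 without control 1. Pachytene and secondary spermatocyte genes (median 0.85, adjusted p = 0.0499), head shaping genes (-0.46, adjusted p = 0.0405) and sex-linked families (-0.58, adjusted p = 0.0499) passed narrowly (adjusted p = 0.565, 0.458 and 0.386 with an estimated correlation). Quantile normalization ended all 3 calls (adjusted p = 0.0625, 0.0977 and 0.0683), as did a fit of the 4 control libraries alone (0.0854, 0.079 and 0.079) and leaving out single libraries. The highest adjusted p was 0.656 for pachytene genes, without control 1 of steps 1 to 3 and 9 to 16. It was 0.489 for head shaping genes, without control 2 of steps 4 to 8, and 0.496 for the sex-linked families, without control 2 of steps 1 to 3 and 9 to 16. No single gene passed: limma called 0 of 7857, with 832 at an unadjusted p under 0.05, and limma voom 0 of 19797 with 1109. Named genes were Zfp41 (1.93), Sdr39u1 (2.36), Tmem115 (1.85), the inhibin subunit Inha (1.95) and Maf1 (2.34) on the higher side. On the lower side were Olfr742 (-1.92), Adam29 (-2.02), Apoo-ps (-1.98), Olfr112 (-2.13) and the calcium pump regulator Sln (-1.88). Whether both regions came from the same animals is not given.

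In knockout mice the same comparison gave higher proteasome genes, with a median of 0.62 over 33 genes (camera adjusted p = 0.000462; adjusted p = 0.695 with an estimated correlation) and Psma2 at 1.64 ± 0.42 and Psma5 at 1.36 ± 0.51 (n = 2 each). Ribosomal protein genes had a median of 0.48 (adjusted p = 0.0118; adjusted p = 0.695 with an estimated correlation), which was -0.26 without knockout 1 of steps 1 to 3 and 9 to 16 (adjusted p = 0.247), was 1.16 without knockout 2 of that region and lost its call without knockout 2 of steps 4 to 8 (0.228) and without a filter (0.054). The acrosome list had a median of -0.56 here and did not pass (adjusted p = 0.233), and its difference from controls was not past the threshold either (0.40, adjusted p = 0.0826). Limma called 0 of 7857 single genes, with 816 at an unadjusted p under 0.05, and limma voom 0 of 19797 with 1831. Named genes were Rabggtb (2.44), Vmn1r40 (2.76), Timp1 (2.11), Trav9n-1 (2.18) and the fatty acid binding protein Fabp5 (1.96) on the higher side, and Sertad4 (-2.38), the meiotic kinase Mos (-2.95), Tmem81 (-3.48), AL671922.1 (-2.27) and Olfr181 (-2.45) on the lower side.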

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

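Tests chosen only after their result was seen were those of the scaling of the libraries, of single libraries and of the somatic cell share.

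The 6 whole testis libraries have 10 splits into 3 and 3, of which 4, the real one included, part all 3 same-numbered pairs and 6 part 1 pair. Both numbers are too few for a share under 0.05. Each split other than the real one sets 2 libraries of one genotype with 1 of the other and so can keep part of a genotype difference. It also moves that difference into the spread within its groups, which makes calls of single genes unlikely there.

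The genotype difference of Y-linked genes was 0.7177 higher (log2 median, 19 genes) in captured tissue of steps 1 to 3 and 9 to 16 than in that of steps 4 to 8 by the test of the difference itself, a call lost with an estimated correlation (adjusted p = 0.472), by fry (0.661) and without control 1 or knockout 2 of steps 4 to 8 (0.68 and 0.66, adjusted p = 0.0552 and 0.0962), and the value was 0.47 without knockout 1 of the other region and 0.033 without a filter.

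The genotype difference of 213 X-linked genes also differed between the captured regions, by 0.5514 (log2 median), because they were lower in knockouts in steps 4 to 8 (-0.72) and not past the threshold in the other region (-0.080, and with libraries scaled to a common sum 0.15 against 0.30 for all genes, a pass towards lower). No single library carried this gap, as it stayed at 0.4332 or higher without each, and relative to all genes it stayed at 0.5104 or more under 3 scalings, of which median centring cannot change it. Another mix of spermatid steps in the captured cells was tested only for the fall in steps 4 to 8. There X-linked genes lay at -0.6789 relative to autosomal genes with like levels and like region differences in controls (95% interval over resampled genes -0.8072 to -0.5868). The gap itself was not tested in this way, and each region pools several steps, so another mix stays open for the gap. The gap may depend on which genes are measured, since it was 0.020 without a filter (adjusted p = 0.108), X-linked genes with a mean RPKM of at least 5 were lower in both regions (-1.25 and -0.81) and their gap of 0.41 did not pass (adjusted p = 0.241), nor did the full gap with an estimated correlation (adjusted p = 0.131). A stronger effect of the genotype on X-linked genes in round spermatids of steps 4 to 8 thus stays a hypothesis.

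The loss of X-linked genes in whole testis kept 80 or more lower calls under the scalings, against 81. This count cannot decide on scaling, as the scalings lowered the median of all genes from 0.09006 to 0.002742 or less. A shift down can hardly remove lower calls. X-linked genes stayed below all genes, with medians of -0.589 against 0.002742 with a common sum and -0.3253 against 0.001616 with quantile normalization. Median centring cannot change that gap. Closeness to the altered locus did not explain the loss. Of X-linked genes over 20 Mb from Tsga8 42.86% were lower, and of those nearer 45.76%. Fewer spermatids in the tissue would lower autosomal genes alike, yet X-linked genes lay at -0.5371 relative to autosomal genes matched on level and on enrichment in captured spermatids (148 genes, 95% interval over resampled genes -0.7168 to -0.3358). That enrichment also holds the difference between kits, and each region pools several steps, so a loss of particular steps stays open. Only 1 of the 10 splits, the real one, gave 81 X-linked genes in one direction (highest other 0) or a median of this size (0.3049, highest other 0.1622), while camera called the X list in the 9 others too (adjusted p = 6.75e-22 to 0.0147). A lower output of X-linked genes in knockout spermatids is a candidate explanation, found and tested on the same data.

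Of the calls in whole testis 66.87% were higher, and at most 42.09% were over 3 scalings, but these move the median of all genes to 0 and so set the balance themselves. The deposited scale stays open as a possible source, since reads in genes were 96.235 to 97.452% of the RPKM denominator in controls and 98.576 to 101.038% in knockouts, which runs the same way. Gene span and GC content stay open too, since removing both trends keeps the median of all genes (0.0905 before and 0.09307 after) and so tests little of the balance, with 79.44% of calls higher against 67.8% before in the fit with the replicate block and 68.03% against 67.24% without it. A higher share of somatic cells stays open, as medians of Sertoli (0.41), Leydig (0.20) and peritubular (0.22) markers were above that of all genes and differed by at most 1.89 standard errors. Only 1 of the 10 splits, the real one, gave as many calls (501), higher calls (335) or lower calls (166), with 0 as the highest other in each, and 7 gave as many lists called by camera (7 in the real one, highest other 11).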

How the results depend on the processing

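Added after the data were seen were limma voom on recovered reads, the X chromosome list without Tsga8 and its families, and whole testis without both libraries numbered 1. A sum over repeated symbols was not run because 0 symbols repeated. In whole testis, 501 genes were called (335 higher, 166 lower, 81 of them X-linked). Fewer were called with a log2 change of at least 1 (50: 13 higher, 37 lower, 29 X-linked), which a size threshold brings by construction, without a filter (166, with 49 higher), at a mean RPKM of at least 5 (216: 166 higher, 50 lower, 29 X-linked), where fewer genes were tested, and with libraries scaled to a common sum (222, with 91 higher). Median centring gave 194 higher and 310 lower, and quantile normalization 157 higher. More were called with quality weights (4722: 3622 higher, 1100 lower), with limma voom (2399: 796 higher, 1603 lower, 237 X-linked), which tested more genes, and without both libraries numbered 1 (2674: 2161 higher, 513 lower). Leaving out single libraries gave 68 to 1466 calls, 16 to 1245 higher, 45 to 332 lower and 38 to 78 X-linked. For the scalings, the weights and the left-out libraries the cause was not tested. Without any one control, only 126 of the 166 lower genes were still tested, since the filter still asked for 3 libraries. Without any one knockout, 312 of the 335 higher genes were still tested. The fit with the replicate number as a block gave 511 higher genes, with 285 of the 335 among them, ended the calls of Hspb1 (adjusted p = 0.0595) and, in captured controls, of the pachytene list (0.0535), and changed no other call of a named gene or list.

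The X chromosome list in whole testis was past the threshold under 20 of 21 alternatives, the exception being the estimated correlation (-0.30, adjusted p = 0.0812; all alternatives 2.86e-57 to 0.0812). Tsga8 in steps 4 to 8 did not pass (-5.79), but was the 1 gene called at a mean RPKM of at least 5 (-5.79, adjusted p = 0.013), with median centring (-5.80, 0.0272), without an intensity trend (-5.79, 0.0383) and with quality weights (-5.79, 0.0207), over a range of 0.013 to 0.939. Without single libraries it ranged from -6.08 to -5.50, with 0 to 1 genes called. The X list in steps 1 to 3 and 9 to 16 (-0.080) passed at a mean RPKM of at least 5 (-0.81, adjusted p = 2.59e-10), with a common sum (0.15, 0.00463) and without knockout 1 of that region (-0.14, 0.0279), and ranged from -0.17 to 0.15 without single libraries (all alternatives 2.59e-10 to 0.821). The ribosomal list between regions of knockouts turned to -0.26 without knockout 1 of steps 1 to 3 and 9 to 16 (adjusted p = 0.247), and ranged from -0.26 to 1.16 without single libraries. Shared genes rose from 0 to 27, 24 and 16 at an unadjusted p under 0.01, a looser threshold. Those of whole testis and steps 4 to 8 alone also rose to 1 at a mean RPKM of at least 5. The cause was not tested for the others. Scaling to a common sum moved the median of all genes from 0.013 to 0.17 in steps 4 to 8, from 0.043 to 0.30 in the other region and from 0.039 to -0.14 between regions of controls.

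Of 29 list calls over all comparisons, 2 held with an estimated correlation, 5 with fry, 23 to 27 under the 3 scalings and 13 without each library in turn. Among the 20 named genes called in whole testis, 8 of 10 lower and 0 of 10 higher ones held under every alternative in which they were tested. Dusp21 was tested in 14 alternatives, against 18 for Tsga8. The 48 named values that did not pass kept their sign in all 902 refits, but their selection made this likely. They were named by smallest p per direction and, outside the difference between regions, for groups that did not overlap. Captured tissue had 2 libraries per group and a wider spread between replicates than whole testis. In steps 4 to 8, simulated changes of 1 on the log2 scale were recovered for 0% of genes, of 2 for 31.2% and of 3 for 60.9%.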

Other observations

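The test of spermatid enrichment across X-linked genes and its autosomal comparison were planned before the result was seen. The split into 3 groups and the value for the other captured region were chosen after it.

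X-linked genes were not all affected alike in knockout whole testis. Those least enriched in captured spermatids of controls had a median log2 difference of 0.097, close to the 0.090 of all tested genes, with 9 of 49 called lower. The middle group stood at -0.55 with 32 of 49 lower, and the most enriched group at -0.87 with 36 of 49 lower. Enrichment is the ratio of the level in control spermatids of steps 4 to 8 to that in control whole testis, which differ in library kit.

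The hypothesis that X-linked genes most enriched in spermatids fall most was tested across 147 genes other than Tsga8. Spearman's rho was -0.5566 (Pearson's r -0.51; two-sided permutation test p = 1e-05, the smallest that 100000 permutations can give). Genes are not independent replicates, and the control whole testis values enter both measures, which by itself pushes rho upwards. Across 6329 autosomal genes rho was 0.048, and autosomal sets of the same size gave -0.11 to 0.20. With enrichment taken from steps 1 to 3 and 9 to 16, rho was -0.35. These values are consistent with a reduced output of the X chromosome in knockout spermatids, but other differences between X-linked genes of high and low enrichment could give the same order.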
